A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

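The series compared the transcriptomes of a wild-type strain of the yeast Saccharomyces cerevisiae, HFY114, and of a strain lacking the gene EDC3. Per the labels, cells were grown in rich medium (YEPD) at 30 °C, RNA was extracted with hot phenol, and biotinylated cRNA was made from 6 µg of total RNA. Each of the 10 samples was hybridised to its own Affymetrix Yeast Genome S98 array, on which a gene is measured by one or more probe sets, each a group of short oligonucleotides. There were 5 arrays per strain. The labels number them as biological replicates and give same-numbered arrays of the strains the same letter; the numbers are called experiments 1 to 5 here.

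The deposited values are intensities: per the labels' processing notes, the authors obtained one MAS5 signal per probe set and array, with the software version not given in the sources used here. From the values, the signals are on a linear scale and each array had been scaled to a common level, since the 2%-trimmed means of the arrays differed by 0.0186% at most. This scaling was kept. The value table holds no detection calls and no background level, so a low signal cannot be told from none by the table alone. Probe-level intensities were not analysed here, so a choice of probes or of background correction within MAS5 could not be varied. For 8 arrays a deposited record of the instrument settings was read for the chip lot, the pixel size and the number of scans; no expression value comes from these records.

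Of the 9335 probe sets, 60 were control probe sets and left out of the tests. Of the other 9275, 6504 were paired with 1 gene by the platform annotation, 328 with several genes and 2443 with none; a probe set of the last kind is unnamed here and may still measure a gene. Gene symbols were taken through the gene identifiers from a table of RefSeq genes of assembly R64. No coordinates are given, because the build behind the array design is not given in the sources used here; a gene's chromosome was read from its systematic name. Where a gene had several probe sets, the one with the highest mean log2 signal stood for it in gene lists.

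Signals were converted to log2 without an offset; 156 signals of 0 were raised to 0.1, the smallest positive signal. The dimmest 30% of the probe sets by mean log2 signal over all arrays, which lie under a mean signal of 16.8, were left out, and 6492 were tested, 5413 of them with 1 gene and standing for 5058 genes. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with 5 arrays against 5 and no block. Adjusted p is the Benjamini-Hochberg value over all tested probe sets, two-sided, with a threshold of 0.05. Fold changes are ratios on this log2 scale and errors are limma's standard errors (SE) unless SD is written. For single probe sets an exact two-sided permutation test of the difference of mean log2 signals was also run, for which 5 against 5 arrays cannot give a p below 0.00794.

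Gene sets were tested with camera at a preset correlation of 0.01 between genes, on 29 lists of which the 25 with at least 5 measured members entered, and on the 16 chromosomes. The test was repeated with the correlation estimated from the data, and with fry. RNA quality was measured as the log2 ratio of the 3′ to the 5′ control probe set of SRB4, SPT15 and ACT1. The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took EDC3, YRA1 and RPS28B always; then up to 12 rises and 12 falls among probe sets with 1 gene, an adjusted p under the threshold and the same sign in at least 4 of the 5 experiments; then, if fewer than 10 passed, the probe sets of smallest p up to 10, as values only; and up to 4 members of smallest p per list. Genes named outside this rule are said to be chosen after their values were seen.

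Because the strains share replicate numbers, the pairing was checked. Deviations from the strain means of same-numbered arrays correlated at 0.65, 0.713, 0.475, 0.652 and 0.692 in experiments 1 to 5, across probe sets, and each of the 10 arrays had the same-numbered array as its nearest among those of the other strain. With the shared letters in the labels, this was taken as pairing, and the fit with the experiment as a block is given beside a result where it changed the call or moved a count by over 1.5 times. The chip lot was the same in experiments 2 and 3, differed in experiment 1, was blank for experiment 4 and had no record for experiment 5; it was used as a block with blank and missing records as levels of their own. No files were identical: array correlations on the log2 scale ran from 0.959 to 0.996.

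The scripts were tested on simulated data with 200 of the 6492 probe sets changed. Without the block, limma recovered 47% of the 1.5-fold and 79% of the 2-fold changes with 0 false calls. With the block it recovered 83% and 93%, with 8 false calls. The simulated noise was independent between arrays and between probe sets. The real arrays of experiments 4 and 5 were nearly alike, as given below, so these rates may not hold for the real data. Arrays give no count of molecules, and the number of arrays limits the precision. Alternatives were quantile, median and cyclic loess normalization, an offset of 8.2 on the log scale, no filter or the dimmest 50% left out, eBayes without trend or robust, array weights, the blocks, each array or experiment left out, and the set tests above. Removal of the trend along the probe set number, experiments 4 and 5 averaged as 1 replicate, and fits to experiments 1 to 3 or 4 and 5 alone, without and with the block, were added after seeing the data.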

Results

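Genome-wide RNA levels were measured in wild-type yeast and in a strain without EDC3, which the design text calls isogenic, with 5 arrays of each strain. Edc3 is a cytoplasmic protein that stimulates the removal of the 5′ cap from mRNA, the step before degradation by the exonuclease Xrn1. The comparison asks which transcripts change in level when Edc3 is missing. The sample labels name the deletion strain CFY25 and the design text names it SYY14; the difference could not be resolved here. The median signal of an array lay between 58.2 and 66.8. The labels call the 5 arrays of a strain biological replicates, and the design text calls the experiments independent.

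The arrays of experiments 4 and 5 stood apart from the others. Each strain's mean was subtracted before a principal component analysis. The first component, with 53.2% of the remaining variance, separated these arrays from those of experiments 1 to 3 in both strains alike. The instrument records list a pixel size of 2.5 µm and 1 scan for experiment 4, against 3 µm and 2 scans for experiments 1 and 2. Within a strain, the arrays of experiments 4 and 5 were also nearly alike. Over 2618 probe sets with a mean signal above 200, the median absolute deviation of their log2 difference was 0.09 in wild type and 0.08 in the deletion, against 0.21 to 0.48 for the other pairs of one strain and 0.13 to 0.19 for the arrays of both strains within one experiment. Their strain differences correlated at 0.912 across probe sets, against 0.027 to 0.429 for other pairs of experiments; probe sets are not independent replicates. Whether they come from separate cultures or from one RNA hybridised again is not given in the sources used here, and if it was one RNA, n is 4 and not 5. They were counted as separate replicates, as labelled, and the counts with both averaged as 1 replicate are given beside the main ones. With 4 replicates per strain the exact permutation test cannot go below 0.0286. EDC3, URA1, URA4, both YRA1 probe sets and the RPS28B probe set with the larger difference reached this value. For URA1 and URA4, which were chosen by their limma results on these same arrays, it adds no separate support.

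EDC3 (YEL015W) was lost in the deletion strain. In the fit without the block 3 other genes were called: YRA1 rose, and URA1 and URA4 fell. With the experiments as a block 29 probe sets were called, and these are given further below. The EDC3 signal was 469 ± 8.93 (SD, n = 5) in wild type and 1.38 ± 0.85 (SD, n = 5) in the deletion strain, in which no array exceeded 2.3. That is no more than the signals of the 4 mouse control probe sets, 4.8 at most on the deletion arrays, for which yeast has no target. The measured log2 difference was -8.97 (limma adjusted p = 1.73e-04). Against the highest of the mouse control signals and of the EDC3 signal on each deletion array, EDC3 was at least 222-fold lower there. The labels of all 10 arrays therefore matched the measured EDC3 signal.

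YRA1 (YDR381W) encodes an RNA-binding protein that carries mRNA to the nuclear export receptor Mex67. Its 2 probe sets both rose. The one with the larger rise went from 593 ± 31.7 to 1104 ± 109 (SD, n = 5 each), a 1.86-fold rise with a log2 difference of 0.89 ± 0.09 (SE) and an adjusted p of 6.82e-04. The other went from 641 ± 95.7 to 1009.6 ± 59.6 (SD, n = 5 each), a log2 difference of 0.67 ± 0.10 (SE, adjusted p = 0.0428). All 5 experiments gave a rise for both, and each reached 0.00794, the smallest p of the exact permutation test. The rises of the probe sets differed by 0.23 ± 0.15 on the log2 scale (SD, n = 5 experiments, larger in 4 of 5), and the exact sign-flip test (p = 0.125) cannot go below 0.0625 with 5 experiments, so it does not decide whether they differ. The probes reach whatever YRA1 RNA contains their sequence and do not separate pre-mRNA from mRNA. The call of the probe set with the smaller rise was lost with experiments 4 and 5 averaged (log2 difference 0.63, adjusted p = 0.441; 0.0225 with the block, in a range of 0.00138 to 0.441 over 16 settings), with eBayes without trend (adjusted p = 0.0937) and on leaving out any one array except wild type 2, with log2 differences of 0.62 to 0.75 and an adjusted p of up to 0.182; in the blocked fit it passed without each experiment in turn. With experiments 1 to 3 alone, neither YRA1 probe set passed without the block (log2 differences 0.81 and 0.58, adjusted p = 0.160 and 0.9995), and with the block the one with the larger rise passed (adjusted p = 0.0352) and the other did not (adjusted p = 0.127).

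URA1 (YKL216W), which encodes dihydroorotate dehydrogenase, and URA4 (YLR420W), which encodes dihydroorotase, act in consecutive steps of pyrimidine synthesis. URA1 fell from 1776 ± 142 to 864 ± 90.1 (SD, n = 5 each), with a log2 difference of -1.04 ± 0.09 (SE, adjusted p = 3.08e-04). URA4 fell from 778 ± 34.2 to 527 ± 54.6 (SD, n = 5 each), with a log2 difference of -0.57 ± 0.09 (SE, adjusted p = 0.0428). Both were lower in all 5 experiments, with the smallest exact permutation p of 0.00794. As both genes were chosen by their limma results on these same arrays, this unadjusted p adds no separate support. Other genes of the pathway were looked up after these values were seen. URA6, the uridylate kinase, had a log2 difference of -0.43 ± 0.11 (SE, adjusted p = 0.706) and URA2, the first enzyme of the pathway, of -0.25 ± 0.09 (SE, adjusted p = 0.933), both lower in all 5 experiments and neither past the threshold. URA3 differed by -0.08 ± 0.08 (SE) and URA5 by -0.07 ± 0.07 (SE), and neither passed (adjusted p = 0.999). The URA4 call was lost with experiments 4 and 5 averaged (log2 difference -0.54, adjusted p = 0.441; 0.0225 with the block, in a range of 0.00138 to 0.441 over 16 settings), with eBayes without trend (adjusted p = 0.0937) and on leaving out any one array, with log2 differences of -0.60 to -0.52 and an adjusted p of up to 0.182. With experiments 1 to 3 alone, URA4 did not pass (log2 difference -0.50, adjusted p = 0.651; 0.127 with the block), and URA1 did (adjusted p = 0.0306; 0.00687 with the block).

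**Figure D1:**
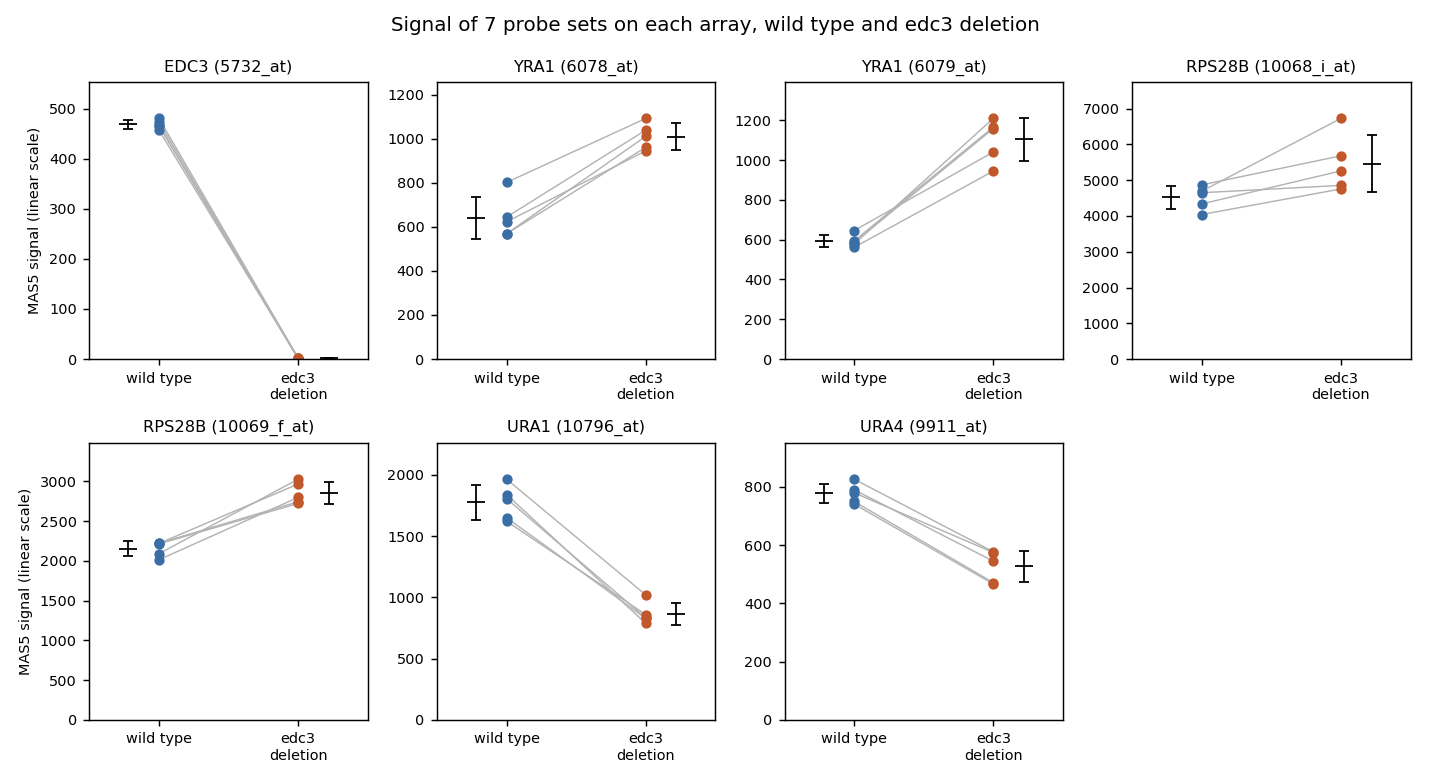
Signal of each array on the linear MAS5 scale for the probe sets of EDC3, YRA1, RPS28B, URA1 and URA4, with a grey line joining the 2 arrays of one experiment and bars for the mean and SD of 5 arrays. The URA1 signals lie between 1621 and 1964 in wild type and between 787 and 1019 in the deletion strain, and EDC3 does not exceed 2.3 in the deletion strain.

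RPS28B (YLR264W) encodes a small-subunit ribosomal protein, and its mRNA is a known target of Edc3-dependent decay. One of its 2 probe sets read 2152 ± 95.02 in wild type and 2852 ± 137 in the deletion strain (SD, n = 5 each), a log2 difference of 0.41 ± 0.07 (SE). The signal was higher in all 5 experiments (exact permutation p = 0.00794), while limma's adjusted p of 0.0643 missed the threshold. With the experiments as a block it passed (adjusted p = 0.0116), but not with the block and experiments 4 and 5 averaged (adjusted p = 0.0617), and over 16 alternative settings the adjusted p ran from 0.00489 to 0.655. The other had a log2 difference of 0.26 ± 0.10 (SE, adjusted p = 0.945; 0.073 with the block), also higher in all 5 experiments. RPS28A, the near-identical paralog, was chosen after these values were seen and differed by 0.07 ± 0.16 and -0.03 ± 0.08 (SE) at its 2 probe sets (exact permutation p = 0.762 and 0.683). Cross-hybridisation between the copies cannot be excluded.

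Over all 6492 probe sets, limma called 5, 2 higher and 3 lower, and these are the probe sets of EDC3, YRA1, URA1 and URA4 described above. An unadjusted p under 0.05 was reached by 313 without the block and by 1501 with it, against 325 expected by chance. The blocked fit gave 632 with experiments 1 to 3 alone and 2886 with experiments 4 and 5 alone, whose arrays are nearly alike. The expected count takes the experiments as independent, so the 1501 does not measure how many probe sets differ. With the experiments as a block, 29 were called, 15 higher and 14 lower, among them the same 5. With experiments 4 and 5 averaged, 3 were called without the block and 8 with it. The 8 were the 5 above with MDH2, PHO89 and MEP2. With the chip lot as a block 10 were called. Within the lot shared by experiments 2 and 3, with 2 arrays against 2 and no block, limma called 0, with 50 at an unadjusted p under 0.05. That fit missed even the deleted EDC3, so its count does not tell whether other genes differ within the lot.

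Among genes called with the block alone, MDH2, the cytosolic malate dehydrogenase of gluconeogenesis, fell, with a log2 difference of -1.22 ± 0.12 (blocked SE, adjusted p = 0.00509; 0.719 without the block). PHO89, a phosphate transporter, rose by 0.88 ± 0.10 (blocked SE, adjusted p = 0.0134; 0.654 without the block). The other genes of this kind, except CEF1, TAD3 and SCW11, were chosen after their values were seen. MEP2, an ammonium permease, fell with a log2 difference of -0.54 ± 0.05 (blocked SE, adjusted p = 0.00351; 0.997 without the block), and GAP1, the general amino acid permease, with one of -0.43 ± 0.06 (blocked SE, adjusted p = 0.0218; 0.654 without the block). CLG1, YNR061C, STF2, SCW11, TMA108 and HXK1 were called higher, by 0.27 to 0.56. CEF1, YLR264C-A, PHD1, TAD3, CBF5 and ERB1 were called lower, with log2 differences from -0.51 to -0.24. YLR264C-A carries a systematic name next to that of RPS28B, and the other called probe sets had no single gene. All of these had the same sign in all 5 experiments.

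**Figure D2:**
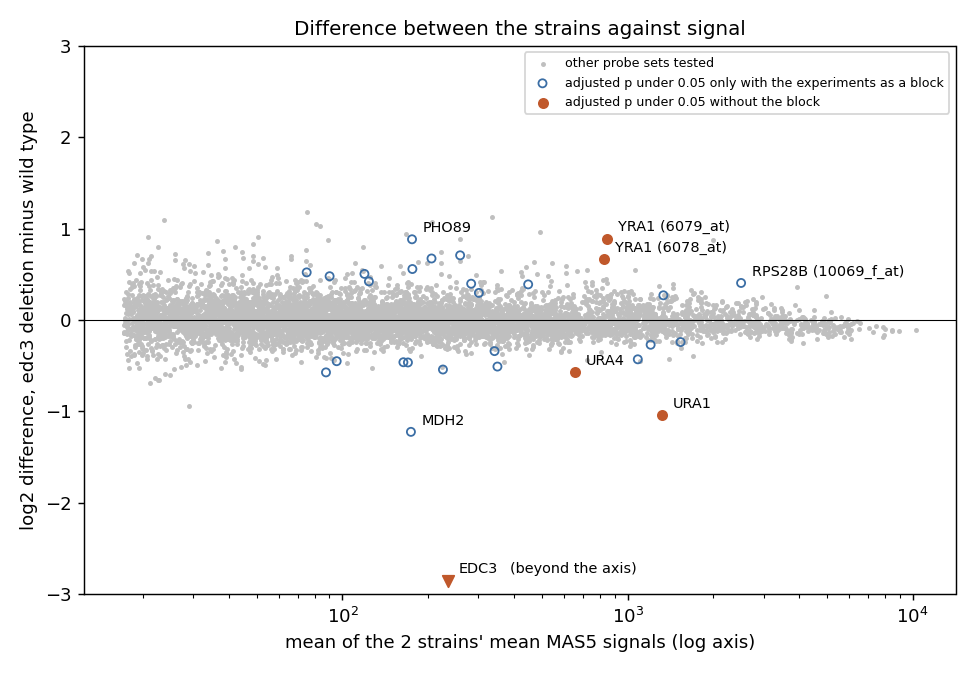
Log2 difference between the deletion strain and wild type against the mean of the 2 strains' mean signals (log axis) for the 6492 probe sets tested. Filled points are the 5 probe sets called without a block, open circles the others among the 29 called with the experiments as a block, and the triangle marks EDC3, whose difference of -8.97 lies beyond the axis.

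The next smallest p values of the fit without the block, given as values and not called, were those of CEF1 (log2 difference -0.45 ± 0.09, SE), the small nucleolar RNA SNR68 (0.90 ± 0.19), YBP1 (0.71 ± 0.16), SNZ1 (-0.46 ± 0.11), COG7 (0.53 ± 0.13) and KEI1 (0.35 ± 0.09). Their adjusted p ran from 0.268 to 0.654.

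Apart from EDC3 itself, which is in none of these lists, no listed gene of the mRNA decay machinery passed limma's test. Of 21 measured genes for decapping and 5′-to-3′ decay, 0 passed, over all probe sets or adjusted over the list alone, with 1 at an unadjusted p under 0.05, and their median log2 difference was 0.05 (camera adjusted p = 0.678). DCP2, the decapping enzyme, differed by -0.20 ± 0.12 (SE) and its partner DCP1 by 0.17 ± 0.12 (SE). PAT1, a decapping activator, differed by 0.95 ± 0.48 (SE), with differences of 2.67 and 2.13 in experiments 4 and 5 and of -0.17 to 0.14 in the others. The 12 deadenylation genes had a median of -0.02 (adjusted p = 0.815) and the 17 genes of the exosome and Ski complex one of -0.02 (adjusted p = 0.662), with 0 passing in either, over all probe sets or adjusted over the list alone, and 0 at an unadjusted p under 0.05. Among 6 measured substrates of nonsense-mediated decay, which is degradation of mRNAs with a premature stop codon, 0 passed and 0 had an unadjusted p under 0.05 (adjusted p = 0.761), and CPA1 differed by -0.35 ± 0.32 (SE). Of 16 mRNA export genes, YRA1 rose, over all probe sets and adjusted over the list alone, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.815). With the block 1 more fell adjusted over the list alone. The export receptor MEX67 differed by -0.22 ± 0.08 (SE, adjusted p = 0.933). The export list was the 1 list called by fry's test for change in either direction (adjusted p = 3.31e-07), and it holds YRA1. Of 78 intron-containing genes outside the ribosome, YRA1 was the 1 that rose, over all probe sets and adjusted over the list alone, with a list median of 0.00 (adjusted p = 0.861); with the block TAD3, a subunit of a tRNA deaminase, fell too, and 2 fell adjusted over the list alone. Of the 2 known Edc3 targets, YRA1 and RPS28B, 1 rose over all probe sets, and adjusted over the list alone both passed. Adjustment over 2 members is slight. RPS28B stood here by its brighter probe set, with the log2 difference of 0.26 and a limma adjusted p of 0.945 over all probe sets. This list had too few members for a set test.

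Ribosome biogenesis genes, whose products assemble ribosomes in the nucleolus, were shifted downwards as a group. Of 67 measured members, 53 were lower, with a median log2 difference of -0.11 and a camera adjusted p of 6.12e-05, which was not kept with an estimated correlation (adjusted p = 0.889 with an estimated correlation). The median was lower in all 5 experiments, from -0.19 to -0.05, and the medians of experiments 2 and 3, which share a chip lot, averaged -0.15. Without the block 0 members passed, over all probe sets or adjusted over the list alone, with 5 at an unadjusted p under 0.05. With the block 2 fell over all probe sets, CBF5 and ERB1, and 18 adjusted over the list alone. EBP2, needed for the large subunit, differed by -0.36 ± 0.09 (SE, adjusted p = 0.654) and UTP14, a small-subunit factor, by -0.28 ± 0.11 (SE, adjusted p = 0.954). The shift was not called with array weights (adjusted p = 0.504), with experiments 4 and 5 alone (adjusted p = 0.293; 0.198 with the block), or on leaving out deletion array 1 or 2 or wild-type array 4 or 5 (adjusted p = 0.0749 to 0.243); over 34 settings the adjusted p ran from 6.16e-14 to 0.504.

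With the experiments as a block, camera called 3 more lists, 0 of them with an estimated correlation. Genes induced in the environmental stress response were higher, with 26 of 32 members up and a median of 0.13 (blocked adjusted p = 0.00217; adjusted p = 0.792 with an estimated correlation; 0.241 without the block). With the block, HXK1, a hexokinase, rose over all probe sets, and adjusted over the list alone 10 rose and 3 fell; without it 0 passed and 0 had an unadjusted p under 0.05. The list held members on both sides. PGM2, a phosphoglucomutase, differed by 0.89 ± 0.58 (SE, 0.19 with the block). The heat shock chaperone SSA4 differed by -0.26 ± 0.17 (SE, 0.07 with the block). Neither passed over all probe sets with the block (limma adjusted p = 0.073 and 0.094). Genes of glycolysis and fermentation had 16 of 18 members lower and a median of -0.07 (blocked adjusted p = 0.0195; adjusted p = 0.837 with an estimated correlation; 0.165 without the block). Of its members 0 passed in either fit, with 0 at an unadjusted p under 0.05 without the block and 5 with it. CDC19, pyruvate kinase, differed by -0.19 ± 0.12 (SE, 0.05 with the block). Genes of the respiratory chain and citrate cycle had 33 of 44 members higher and a median of 0.06 (blocked adjusted p = 0.0433; adjusted p = 0.837 with an estimated correlation; 0.241 without the block). Of its members 0 passed in either fit, with 0 at an unadjusted p under 0.05 without the block and 6 with it. COX7, a subunit of cytochrome c oxidase, differed by 0.17 ± 0.11 (SE, 0.07 with the block).

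The other lists were not called with or without the block. Methionine and sulfur metabolism had 16 of 21 members lower and a median of -0.13 (adjusted p = 0.0597), with SUL2, a sulfate permease, at -0.34 ± 0.12 (SE) and MET3, ATP sulfurylase, at -0.28 ± 0.13 (SE). Of its members 0 passed without the block, with 4 at an unadjusted p under 0.05, and with the block 4 fell adjusted over the list alone. In the phosphate regulon, 8 of 14 members were higher (adjusted p = 0.241); PHO89 rose adjusted over the list alone, and with the block 4 rose and 1 fell; SPL2 differed by 0.29 ± 0.13 (SE). Cytoplasmic ribosomal protein genes had a median of -0.03 over 81 members (adjusted p = 0.292), with RPL15B at -0.43 ± 0.13 (SE). Adjusted p was 0.292 for heat shock chaperones, 0.761 for glucose-repressed genes, 0.633 for amino acid biosynthesis, 0.301 for purine and for sterol biosynthesis, and 0.761 for iron and copper uptake. It was 0.861 for G1 and S phase genes, 0.568 for M and early G1 genes and for pheromone response, and 0.761 for a-specific mating genes. Selectable markers (adjusted p = 0.727) and the 6 neighbours of EDC3 (adjusted p = 0.539) were not called either; NPP2, next to EDC3, differed by 0.44 ± 0.16 (SE, adjusted p = 0.933). Without the block 0 members of the lists named from the ribosomal proteins on passed limma's test, over all probe sets or adjusted over the list alone, and an unadjusted p under 0.05 was reached by 3 members each among ribosomal protein and glucose-repressed genes, 2 each among M and early G1 and pheromone genes and 1 each among heat shock, amino acid and neighbour genes, and 0 in the others. With the block and adjusted over the list alone, 2 heat shock chaperones, 1 purine gene and 2 selectable markers fell, 2 neighbours of EDC3 rose, SCW11 rose among M and early G1 genes, and 1 glucose-repressed gene rose while 1 fell. Median and mean differed in sign for mRNA export (-0.03 and 0.03) and glucose-repressed genes (0.01 and -0.07), with camera's direction that of the mean, and for selectable markers (-0.02 and 0.00), with that of the median. For introns and for G1 and S phase genes, camera's direction was down and the median 0.00. Histones (median 0.00), alpha-specific mating genes (-0.16) and meiosis genes (-0.29) had fewer than 5 measured members and were not tested as lists; with the block 1 alpha-specific gene fell adjusted over the list alone.

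Chromosomes were compared because a copy number difference would move all genes of one. Camera called 10 of 16, with VII, VIII and IX higher and I and X to XV lower, and 0 with an estimated correlation (adjusted p = 0.427 to 0.882 with an estimated correlation). The shifts were small: chromosome XI, with the largest, had a median log2 difference of -0.09, with 230 of its 283 genes lower. The difference between the strains also fell along the numbers of the probe sets, which follow the chromosomes in part. Named probe sets had a median of 0.05 between numbers 4000 and 6000 and of -0.08 between 10000 and 12000, and probe sets without a listed gene had 0.06 and -0.08. With this trend removed, 0 chromosomes were called, but the removal can also take out shifts of whole chromosomes.

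**Figure D3:**
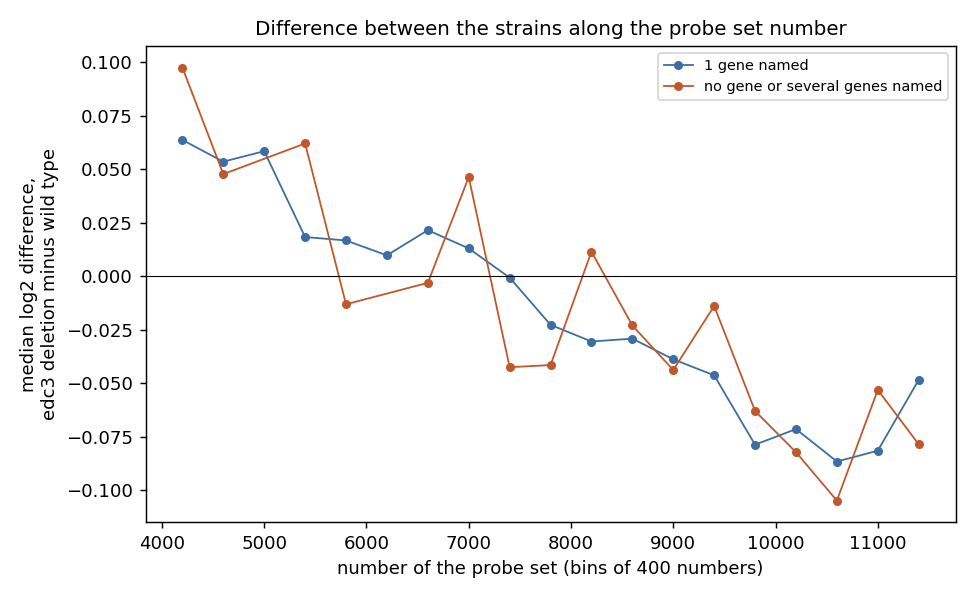
Median log2 difference between the deletion strain and wild type in bins of probe set numbers, for probe sets with 1 named gene and for those with no or several genes. Both lines fall from left to right.

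The RNA quality controls did not separate the strains. Their tests do not use the pairing of the experiments, so a shift within experiments is not excluded. The mean log2 ratio of the 3′ to the 5′ control probe sets was 2.19 ± 0.33 in wild type and 2.01 ± 0.21 in the deletion strain (SD, n = 5 each), a difference of -0.18 (exact permutation p = 0.365). Single controls gave -0.31 for SRB4, -0.16 for SPT15 and -0.07 for ACT1, with adjusted exact permutation p of 0.429 to 0.437.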

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

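No test in this part was chosen after its result was seen, but URA2, URA3, URA8, URA10, FUR4, RPS28A, GAP1 and TMA108 entered it because their values had been seen. For each named probe set or quality ratio and each strain, the gap between the most extreme array and its nearest neighbour was set against the range of the 5 arrays on the log2 scale. Of 288 groups of 5 arrays, 22 had a gap above 0.71 of the range, where chance gives about 14.4. Of these, 6 fell on wild-type array 2.

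VAC8, a neighbour of EDC3, read 6.7 on wild-type array 3 and 209.7 to 252 on the other 4 (gap 0.949 of the range). Its log2 difference was 5.21 in experiment 3 and -0.31 to 0.26 in the others. FUR4, the uracil permease, read 147 on deletion array 3 and 297 to 310 on the others (0.945). RPS28A read 558 on wild-type array 1 at one of its probe sets and 887 to 1018 on the others (0.771). EDC3 read 0.1 on deletion array 3 and 1 to 2.3 on the others (0.734), all at the level of the mouse control probe sets.

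Wild-type array 2 lay apart for ADE16 (918.6 against 989.7 to 998.7, gap 0.892), GTT3 (659.7 against 857 to 919, 0.791), URA3 (313 against 351 to 366, 0.745), SSP1 (33.4 against 18 to 21.1, 0.743), VTC2 (948 against 876 to 895, 0.728) and GAP1 (lowest, against 1259 to 1373, 0.726). Deletion array 2 lay apart for CAF40 (395 against 302 to 316, 0.838), EBP2 (210.3 against 249.8 to 264, 0.752), MET3 (261 against 174 to 194, 0.738) and GFD1 (106 against 74.9 to 82.1, 0.734).

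Wild-type array 1 was highest for URA2 (2404 against 1806 to 1912, 0.8), TMA108 (above 95.7 to 103, 0.76) and URA8 (319 against 244 to 261, 0.751). URA10 was lowest on wild-type array 5 (23.8 against 31.4 to 32.6, 0.881) and KEI1 on wild-type array 4 (158 against 179.9 to 188, 0.762). SUB2 was highest on wild-type array 3 (1395 against 1228 to 1251, 0.854). FAR1 was lowest on deletion array 3 (406 against 484 to 505, 0.8), and MDJ1 was highest on deletion array 1 (236 against 163 to 180.2, 0.732).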

How the results depend on the processing

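The settings that removed the probe set number trend, averaged experiments 4 and 5, took experiments 1 to 3 or 4 and 5 alone, without or with the block, or estimated correlations for chromosomes or with the block were chosen after the data were seen. EDC3, URA1 and the YRA1 probe set with the larger rise kept their sign and call under 16 alternative settings and with each array left out; with experiments 1 to 3 alone and no block YRA1 missed the threshold at both probe sets (log2 differences 0.81 and 0.58), and with the block at the second one (0.58). The count of 5 called probe sets became 3 with eBayes without trend, 106 with array weights, 29 with the replicate block, 37 with the replicate block and quantile normalization, 10 with the chip lot block and 16 with the replicate block and the trend removed. It was 3 with experiments 4 and 5 averaged, 8 with these averaged and the block, 2 with experiments 1 to 3 (3 with the block) and 1263 with experiments 4 and 5, whose arrays are nearly alike (2277 with the block). Leaving out one array gave 3 to 4, and one experiment in the blocked fit 7 to 30, with 8 without experiment 1 or 4, 26 without 3 and 7 without 5. The YRA1 probe set with the smaller rise lost its call without the eBayes trend (log2 difference 0.67) and with experiments 4 and 5 averaged (0.63); with one array left out its difference was 0.62 to 0.75. The RPS28B probe set with the larger difference passed with quantile normalization, alone and with the block (0.41), with the dimmest 50% left out, the replicate block or the lot block (0.41), with array weights (0.46), with the trend removed, alone or with the block (0.48), and with experiments 4 and 5, alone or with the block (0.50), where the other RPS28B probe set passed too with the block (0.40); in the blocked fit with one experiment left out it was 0.37 to 0.43, with 0.43 without experiment 1, 0.40 without 2 and 0.43 without 3 past the threshold. Called lists numbered 2 with median centring, 0 with array weights, 4 with the replicate block, 2 with the block and quantile normalization, 2 with the lot block, 3 with the trend removed and 4 with the block added, 2 with experiments 4 and 5 averaged and 3 with the block added, 3 with experiments 1 to 3, without or with the block, 0 with experiments 4 and 5 and 5 with the block added. An estimated correlation gave 0, with the block too, and fry 0 by direction; leaving out one array gave 0 to 6 and one experiment 3 to 6. Called chromosomes numbered 0 with the trend removed, 0 with the block added, 0 with an estimated correlation, 5 with experiments 4 and 5, without or with the block, and 2 to 11 with one array left out, the 2 without wild-type array 1. With the trend removed, chromosomes I, VII, VIII and IX changed sign at an adjusted p of 0.994; with the block added VII, VIII and XIII did at 0.999 and IX at 0.858. FUR4 was higher by 0.15 with experiments 4 and 5 and the block. Among the set tests, the block changed the calls of 3 lists and of 0 chromosomes. Robust eBayes was not run for gene sets, since camera has no such option. RNA quality kept its sign, from -0.27 to -0.06 with one array left out. For named genes other than EDC3, YRA1 and RPS28B, 4705 values were compared with the main fit. Of these, 4369 kept sign and side of the threshold, 243 passed newly and 14 lost the call. A further 78 changed sign uncalled and 1, the FUR4 value, changed sign and passed. Where a setting changed a result, the cause was not tested. Dim probe sets near a signal of 16.8 have no background level to be judged by.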

Other observations

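Chosen after the result was seen were the tests of chromosome copy number, of the state of URA3, of a single experiment behind the Ty signals, and of other splits for the counts of probe sets, with and without the block, and for the lists with the block. The Ty probe sets are a group defined after their values were seen: 22 probe sets whose listed genes are all unnamed loci of the length of a Ty1 or Ty2 reading frame. Ty1 and Ty2 are retrotransposons present in many near-identical copies, so a probe set reads the family and not one copy. Of the 22, 21 were higher in the deletion strain, with a median log2 difference of 0.26, and 0 passed the threshold with or without the block. Their median was higher in every experiment, at 0.29, 0.13, 0.05, 0.46 and 0.45 in experiments 1 to 5. The mean over the family differed by 0.30, which the spread between arrays does not separate from 0 (exact permutation p = 0.190). That test does not use the pairing of the experiments, so the spread includes differences between them. Camera gave p = 1.04e-08 with the preset correlation and 0.126 with an estimated correlation, or 6.54e-12 and 0.0829 with the block.

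How far a trend along the probe set number accounts for the Ty shift was not settled. In the number range of these probe sets, 74 named probe sets of other genes had a median of 0.0774 (95% interval 0.03 to 0.14), against 0.26. The Ty group was defined after its values were seen, and the interval takes probe sets as replicates, so this comparison does not decide. With experiments 4 and 5, which are nearly alike, left out together the median was 0.16 ± 0.07 (SE, n = 3), which does not decide whether the shift rests on them. A difference in Ty copy number between the strains, or an effect of the deletion on Ty RNA, may lie behind it; neither was tested, and the camera p with an estimated correlation leaves chance open.

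The shifts of whole chromosomes may go with the numbering of the probe sets, whose places on the arrays are not given in the sources used here. Within chromosomes, the log2 difference fell with rising probe set number (permutation p = 0.01). After removal of the trend 0 chromosomes were called, against 10 before. As the numbers follow the chromosomes in part, the removal can also take out shifts of whole chromosomes, so this count does not decide. A gain or loss of a chromosome would need a median of 0.585 for a 1.5-fold change, and the largest median in size was 0.0875, which argues against a copy number difference in the whole culture. What gives rise to the trend was not tested.

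A hypothesis for the lower URA1 and URA4 is that the strains differ in the state of URA3, the gene often used as a selectable marker. Ppr1 activates URA1, URA3 and URA4 when pathway intermediates accumulate, as in cells without a working URA3. The probe set number trend argues little: after its removal URA4, the smaller fall, still differed by -0.50 and URA1 by -0.96. PPR1 mRNA differed by -0.0125, with a 95% interval from -0.2955 to 0.27. This gives no sign of a lower PPR1 level, but a small fall is not excluded. How large a fall would lower URA1 and URA4 was not tested, so PPR1 is not set aside as a cause. URA10, another Ppr1 target, differed by -0.12, with an interval from -0.47 to 0.22 that decides nothing. URA3 had mean signals of 351 in wild type and 332 in the deletion strain. A control probe set for URA3 read 610.5 and 566 (log2 difference -0.11, exact permutation p = 0.325). These signals show URA3 RNA in both strains, but not whether the gene works. The difference of URA3 exceeded the mean of those of URA1 and URA4 by 0.73 ± 0.10 (SD, n = 5), but 90.3% of all tested probe sets exceeded it by over 0.3 in all 5 experiments as well, so this decides nothing, and the state of URA3, the genotypes and an effect of the missing Edc3 itself stay open.

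The counts of calls were set against other splits. Of the 126 splits of the 10 arrays into 5 and 5, 100 were drawn with a fixed seed, and 4 of them called at least 5 probe sets, the real one included; the highest of the others was 1232. This share is under 5% among those drawn, but so close to it that chance is not firmly excluded, as the share over all 126 was not computed. Of the 4 drawn splits that put all arrays of experiments 4 and 5 on one side, out of 6 possible, 3 called as many as the real one, up to 1232, and 1 called fewer, with 0 the lowest; all other splits except the real one called 0, which points to the structure of the experiments described above. Among the 16 ways to swap the strains within experiments, the real one called 29 with the block and the highest of the others 0, and without the block the real one called 5 and the highest of the others 0; 16 ways are too few for a share under 5%, with 1 of 16 as large. For gene lists, 88 of 100 splits called at least the 1 list of the real split, with 11 the highest of the others, so chance is not excluded for this count, which takes any list and parts the experiments. Among the 16 swaps within experiments, 7 called at least the 4 lists of the real one with the block, with 9 the highest of the others, and the ribosome biogenesis median was 0.11 in size in the real one and at most 0.10 in the others; 16 ways are again too few for a share under 5%. For chromosomes, 16 of 100 called at least the 10 of the real split, with 12 the highest of the others, so chance is not excluded for that count either. These splits part the experiments too, and swaps within experiments are not given here for chromosomes.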
